A study of Pisaster ochraceus with 50 samples.

How the data were processed

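Gene expression was measured by RNA sequencing of tissue biopsies from the ochre sea star Pisaster ochraceus, an intertidal predator of the Pacific coast of North America. The animals were collected in August at Point Reyes, 15 at McClures Beach and 2 at Lifeboat House. Of these 17 animals, 15 were asymptomatic and 2 showed signs of sea star wasting disease, a condition in which sea stars develop lesions, lose arms and disintegrate. Dermis (body wall), tube feet (the hydraulic podia used for locomotion) and pyloric caecum (the digestive gland) were sampled. This gave 48 libraries: 16 of dermis, 15 of tube feet and 17 of pyloric caecum. A further 2 tube feet libraries, 1 per disease label, came from 1 animal of Friday Harbor that is not among the 17, and they were kept apart from the comparisons. The labels name 5 batches.

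Per the labels, RNA was extracted with the Qiagen RNeasy Mini Kit and libraries were made with the Illumina TruSeq RNA Library Prep Kit v2. The authors trimmed reads with Trim Galore 0.4.4, aligned them with TopHat2 2.0.13, handled alignments with SAMtools 0.1.19 and named edgeR for the tests of expression. The deposited files hold raw counts, 1 whole number per gene for 21777 genes, followed by 5 summary lines, 21782 lines per file. The form of the summary lines is that of a read counter that sets aside reads that meet no gene or several genes. The counter, its strand setting, the genome build and the annotation are not given in the sources used here. The files do not pair IDs with names, so genes are given by ID and no position or function can be stated. Reads that met no annotated gene made up 85.2% ± 2.17 of the counted lines in dermis (SD, n = 16), 79.7% ± 0.903 in tube feet (n = 15) and 74.5% ± 2.94 in pyloric caecum (n = 17). What these reads are is not given in the sources used here, and their share differed between tissues.

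Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Each main comparison was an edgeR quasi-likelihood F-test with TMM normalization, on genes with a mean of at least 1 CPM (gene reads scaled to a common library size) over the libraries fitted, at a Benjamini-Hochberg false discovery rate under 0.01. These settings are those stated in the study's design text. The filter kept at least 99.8% of the gene reads in each fit. Standard errors are the log2 fold change divided by the square root of F. The 3 tissues were compared in 1 fit of the 48 libraries. The difference of the disease effect between tissues was tested as an interaction in a fit of tissue and status together. Symptomatic and asymptomatic libraries were compared within each tissue, and so were the 4 size classes of the asymptomatic animals, each against the mean of the other classes and small against x-large. Adjusted p-values named below come from these edgeR fits unless another tool is named.

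Genes were named by a fixed rule. Among genes past the false discovery rate, with a mean of at least 10 CPM in the higher group and no overlap of the libraries' CPM between the groups, the 2 with the largest log2 fold change in each direction were named per tissue contrast, per disease contrast and for small against x-large. Other genes are named only where a count was 5 or fewer or a gene was singled out, and these were chosen after their values were seen. Lists of 100 tissue-enriched genes, those higher in 1 tissue than in both others in asymptomatic libraries, were tested in each disease contrast with camera (preset inter-gene correlation of 0.01) and fry, 9 tests in all, at an adjusted p of 0.05. These lists were chosen on the same libraries, so they are not independent evidence. The comparisons, their tests, the naming rule, the list rule and most alternatives were chosen before the data were examined.

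The precision of each value follows from depth and replicate number. Gene reads per library ranged from 373930 to 1105420, so 1 read is about 1 to 3 CPM. A fold against a group with no reads is given as at least N-fold, against a floor of 3 reads over the group. With 1 to 3 reads in a group, the ratio of reads per depth is given with its exact 95% interval. Floors and intervals cover counting error only, because reads are amplified copies and not independent molecules. The tests were tried on simulated data in which 200 genes had been changed by 2, 4 or 8-fold. For pyloric caecum against dermis, 25.4%, 70.1% and 81.8% of them were called at these folds. For symptomatic against asymptomatic dermis the shares were 0%, 16.4% and 33.3%, for pyloric caecum 2.99%, 4.48% and 39.4%, and for tube feet 0%, 19.4% and 53.0%. At most 3 unchanged genes were called in any simulation, in small against x-large dermis, where 39 genes were called in all. The simulated genes were drawn independently, without batch or animal effects. The simulations thus do not show how many false calls such effects give. For small against x-large, 0% were called at 2-fold, 7.46% to 19.4% at 4-fold and 34.8% to 43.9% at 8-fold over the tissues. Disease and size differences of 2-fold and 4-fold are thus mostly out of reach of these group sizes, and many of 8-fold are missed too.

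Alternatives were DESeq2 size factors in place of TMM, the DESeq2 Wald test, no filter on low counts, filterByExpr, a minimum fold of 2 (glmTreat), batch as a covariate, animal as a replicate block in edgeR and in limma-voom with duplicateCorrelation, size class as a covariate, a robust fit, subsets of animals, lists of 50 and 200 genes, an estimated inter-gene correlation, other pseudocounts, and leaving out each library of the smaller comparisons in turn. The DESeq2 Wald test was run on the tissue, disease and size comparisons with their full sets of libraries, not on the subsets. A fit that leaves 1 symptomatic animal, or 1 small library in tube feet, takes the spread of that lone library to be that of the other groups. Chosen after seeing the data were fits without the tube feet library of M0D055228P, with a low share of tube feet genes, and without the dermis library of M0D055226N, with many reads in few genes, and the number of genes with a read as a covariate in dermis. Libraries of 1 animal were checked for pairing and no duplicated library was found. For the Friday Harbor pair, differences of log2(CPM + 2) were set against 10000 random lists matched on expression.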

Results

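The data are 50 tissue transcriptomes of Pisaster ochraceus, 48 of them from 17 Point Reyes animals. In the asymptomatic animals, the size classes small, medium, large and x-large held 3, 3, 5 and 3 dermis libraries, 2, 3, 5 and 3 tube feet libraries, and 3, 3, 5 and 4 pyloric caecum libraries. Of the symptomatic animals, M0D055233U was a large animal from McClures Beach sequenced in batch 2, and M0D055236X was a medium animal from Lifeboat House sequenced in batch 5. Gene reads per library averaged 476438 ± 75081 in dermis (SD, n = 16), 672875 ± 33858 in tube feet (n = 15) and 880692 ± 121712 in pyloric caecum (n = 17). Genes with a read averaged 12330 in dermis, 14525 in tube feet and 12898 in pyloric caecum.

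Tissue separated the libraries first. The leading principal component held 42.6% of the variance and the next 15.1%. The component after that held 4.38% and set the symptomatic dermis libraries (scores of -67.7 and -79.6) and the symptomatic pyloric caecum libraries (-80.7 and -69.3) apart from the asymptomatic libraries of these tissues, which lay between -17.4 and 27.3 in dermis and between -13.9 and 35.1 in pyloric caecum. The symptomatic tube feet of Point Reyes lay at -10.7 and -33.5, against -5.10 to 19.8 in asymptomatic ones. Of the Friday Harbor pair, the library labelled asymptomatic lay at -20.4, beyond 1 of the symptomatic ones, and the one labelled symptomatic at -1.60. In pyloric caecum 1 gene, g13155, took 24.3% ± 8.99 of the gene reads (SD, n = 17), and g5054 took 4.23%. The gene with the most reads was g15 in dermis, with 4.43% ± 3.07 (n = 16), and also in tube feet, with 2.29% ± 0.870 (n = 15).

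**Figure D1:**
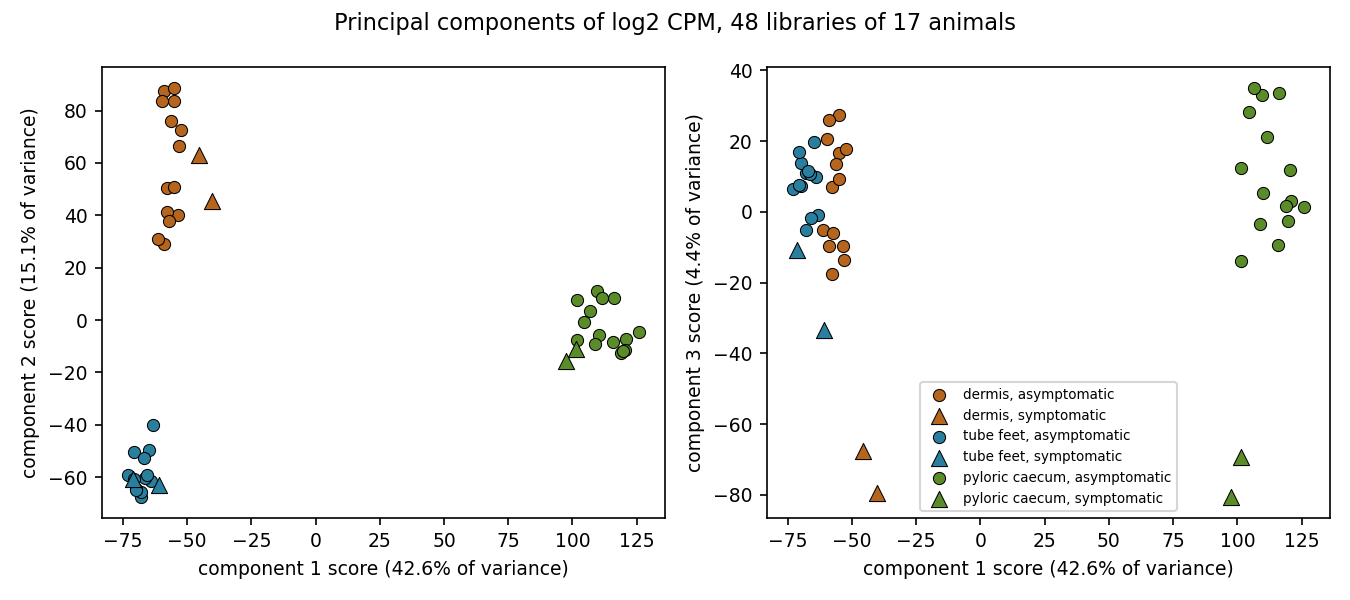
Principal component scores of the 48 Point Reyes libraries, with tissue by colour and disease status by symbol, and the share of variance on each axis. The Friday Harbor pair is not drawn. The leading components, with 42.6% and 15.1% of the variance, part the tissues, and symptomatic dermis lies at -67.7 and -79.6 on the axis that holds 4.38%.

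The tissue comparison asked which genes mark dermis, tube feet and pyloric caecum. Pyloric caecum stood furthest apart: 6013 of 15245 genes differed between pyloric caecum and dermis (39.4%), 2990 higher and 3023 lower, and 1355 of them by more than 16-fold. In pyloric caecum, g2465 reached 88.9 ± 32.0 CPM (SD, n = 17) and had no read in the 16 dermis libraries, at least 239-fold higher (adjusted p = 1.3e-18). Likewise g4878 reached 84.4 ± 75.4 CPM with no read in dermis, at least 227-fold higher (adjusted p = 8.2e-15). Among genes lower in pyloric caecum than in dermis, g15063 stood at 0.384 against 805 ± 1132 CPM, a log2 fold change of -10.48 ± 0.69 (SE; adjusted p = 8.6e-20), and g4218 at 0.410 against 512 ± 780 CPM, -9.82 ± 0.78 (adjusted p = 1.1e-16).

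Pyloric caecum and tube feet differed at 5781 genes, 2544 higher and 3237 lower in pyloric caecum, 1515 of them by more than 16-fold. The gene g2501 was abundant in pyloric caecum, at 12519 ± 5430 CPM against 12.02 ± 6.63 in tube feet (SD, n = 17 and 15; log2 fold change 10.01 ± 0.37, adjusted p = 8.4e-31), and g12629 reached 926 ± 460 against 0.720 CPM (10.06 ± 0.51, adjusted p = 7.6e-25). In the other direction, g5679 stood at 1.59 CPM in pyloric caecum against 988 ± 344 in tube feet (-9.05 ± 0.42, adjusted p = 1.5e-26). The gene g13943 had no read in 17 pyloric caecum libraries against 95.5 ± 46.1 CPM in tube feet, at least 336-fold lower (adjusted p = 2.3e-21).

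Dermis and tube feet were closer, with 4520 genes past the threshold, 1913 higher and 2607 lower in dermis (1606 and 1363 with filterByExpr), and 401 by more than 16-fold. In dermis g263 reached 923 ± 1113 CPM against 1.46 in tube feet (SD, n = 16 and 15; log2 fold change 9.16 ± 0.68, adjusted p = 6.1e-17), and g2463 reached 158 ± 162 CPM against 2 reads over the tube feet libraries, a ratio of 1101 (95% interval 304 to 9103; adjusted p = 1.6e-21). In tube feet g4198 reached 1591 ± 515 CPM against 5.60 ± 4.31 in dermis (-8.12 ± 0.32, adjusted p = 2.7e-28). The gene g5326 had 1 read in dermis against 91.1 ± 52.1 CPM in tube feet, a ratio of 750 (95% interval 134 to 29642; adjusted p = 1.1e-21).

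Across the 3 contrasts, 8848 genes passed the threshold in at least 1 and 1029 in all 3. Genes higher in 1 tissue than in both others numbered 1801 in pyloric caecum, 1256 in tube feet and 1049 in dermis, and genes lower than in both others numbered 1838, 628 and 894. With animal as replicate block, the paired fit gave 6055 genes for pyloric caecum against dermis, 5914 for pyloric caecum against tube feet and 4685 for dermis against tube feet. Each of the 12 genes named for these contrasts kept its call in all 12 alternatives run. Only a stricter filter (filterByExpr: 3815, 3489 and 2969) and a minimum fold of 2 (3089, 3370 and 1284) moved the counts by more than 1.5 times.

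**Figure D2:**
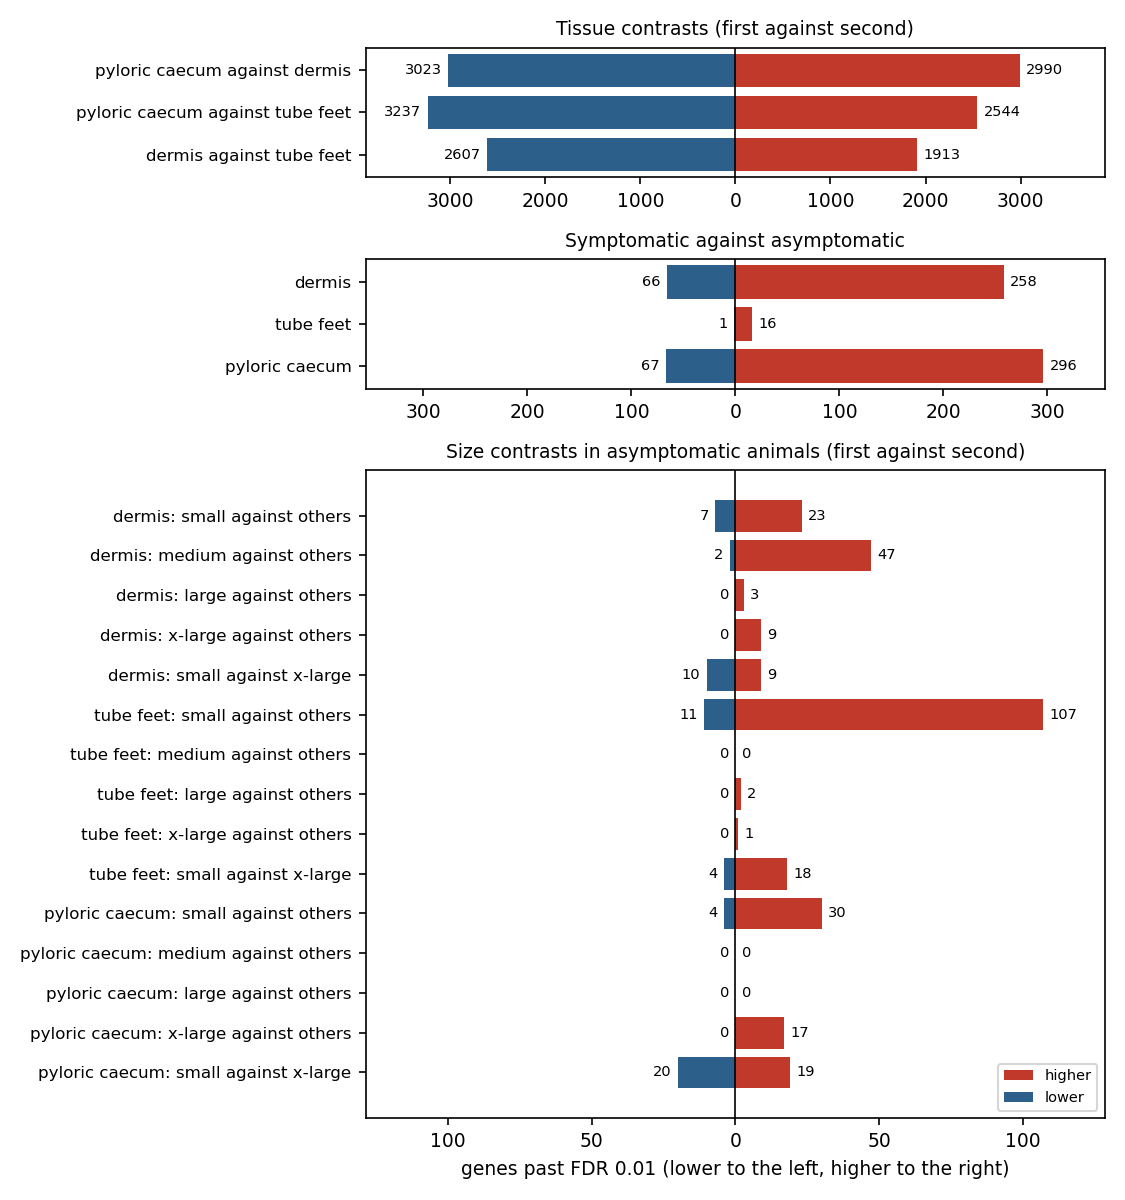
Number of genes past an adjusted p of 0.01 in each comparison, with higher and lower genes drawn to opposite sides, for the tissue, disease and size contrasts. Tissue contrasts reach 6013 genes, disease contrasts 363 and size contrasts 118.

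The disease comparison asked which genes differ between symptomatic and asymptomatic animals in each tissue. In dermis 324 of 14257 genes passed, 258 higher and 66 lower in symptomatic animals, 292 of them by more than 4-fold and 100 by more than 16-fold. The gene g20988 rose from 11.2 ± 9.17 CPM (SD, n = 14) to 3609 ± 687 (n = 2), a log2 fold change of 8.36 ± 0.43 (SE; adjusted p = 3.0e-14), and g3834 from 3.11 ± 7.24 to 905 ± 178 CPM (8.32 ± 0.59, adjusted p = 1.8e-11). In the symptomatic libraries, g4975 had no read against 95.9 ± 42.0 CPM, at least 30.8-fold lower (adjusted p = 5.8e-06), and g20791 had none against 31.3 ± 18.6 CPM, at least 10.7-fold lower (adjusted p = 6.8e-04). The count was 152 without M0D055233U, 150 without M0D055236X, 147 in McClures Beach libraries only and 196 with batch as a covariate, and the DESeq2 Wald test gave 272 higher and 129 lower. The call of g20791 was lost in these fits with 1 symptomatic animal (adjusted p = 0.0341 without M0D055233U, 0.0316 without M0D055236X and 0.0431 at McClures Beach).

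In pyloric caecum 363 of 13205 genes passed, 296 higher and 67 lower in symptomatic animals, and 75 by more than 16-fold. The gene g21523 rose from 6.34 ± 5.94 CPM (SD, n = 15) to 510 ± 437 (n = 2; log2 fold change 6.27 ± 0.59, adjusted p = 1.6e-07), and g5343 from 1.38 ± 3.22 to 240 ± 289 CPM, with 35.7 and 445 CPM in the symptomatic libraries (7.26 ± 0.71, adjusted p = 2.3e-07). The genes g7145 and g14605 had no read in either symptomatic library, against 89.2 ± 54.4 and 19.8 ± 11.6 CPM, at least 53.0-fold and at least 11.6-fold lower (adjusted p = 0.0023 and 0.0063). The count was 69 without M0D055233U, 188 without M0D055236X, 183 at McClures Beach, 27 with batch as a covariate and 550 by the DESeq2 Wald test (342 higher and 208 lower). With batch, g21523 (adjusted p = 0.0213), g7145 (0.0275) and g14605 (0.0289) lost their calls, and g14605 also did with size class (0.0112). Without M0D055233U, g7145 (0.0967) and g14605 (0.159) lost theirs, without M0D055236X so did g7145 (0.0445), g14605 (0.0769) and g5343 (4.51, adjusted p = 0.0109), and g5343 also did by DESeq2 (0.0161). At McClures Beach alone g5343 (0.0149), g7145 (0.0548) and g14605 (0.0873) missed the threshold.

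Tube feet differed least, with 17 of 15176 genes past the threshold, 16 higher and 1 lower in symptomatic animals. The gene g12779 rose from 1.46 ± 1.65 CPM (SD, n = 13) to 38.1 ± 45.5 (n = 2), with 5.93 and 70.3 CPM in the symptomatic libraries, a log2 fold change of 4.52 ± 0.69 (adjusted p = 0.0028). The gene g14445 rose from 26.2 ± 24.4 to 510 ± 573 CPM, with 915 and 106 CPM in the symptomatic libraries (4.27 ± 0.62, adjusted p = 0.0013), and g12588 had no read in symptomatic tube feet against 14.8 ± 5.53 CPM, at least 6.99-fold lower (adjusted p = 0.0072). Over these 17 genes, which were called on the same libraries, the median log2 difference from the asymptomatic mean was 1.36 in M0D055233U and 3.79 in M0D055236X. The count was 3 without M0D055236X, 11 without the asymptomatic animal M0D055231S, 1 with batch, 1 at McClures Beach, 8 with size class, 7 in the robust fit, 51 by DESeq2 (34 higher and 17 lower), and 0 by edgeR with the Friday Harbor pair added (999 at an unadjusted p under 0.05). The call of g12779 was lost without M0D055236X (log2 fold change 1.87, adjusted p = 0.945), at McClures Beach (1.96, 0.948), with batch (0.0982), with size class (0.0480) and with the Friday Harbor pair (0.0287). That of g14445 was lost without M0D055233U (1.996, 0.512), with batch (0.142), by DESeq2 (0.0125), in the robust fit (0.0330) and with the Friday Harbor pair (1.07, 0.943), so the size of both rises rests mainly on 1 library each. That of g12588 was lost in 16 of 23 alternatives, with adjusted p up to 0.467: without M0D055233U (0.0822) or M0D055236X (0.344), and narrowly (0.0104 to 0.0145) without M0D055220H, M0D055222J, M0D055223K, M0D055224L, M0D055225M, M0D055227O, M0D055230R, M0D055231S or M0D055234V, among others.

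The symptomatic dermis and pyloric caecum shared many genes. Of 12280 genes tested in both tissues, 225 were called higher in dermis and 282 in pyloric caecum, and 74 in both, against 5.17 for independent lists. For lower genes the counts were 49, 49 and 6, against 0.196. A single gene, g9519, was called in opposite directions, rising in dermis (2.55 ± 0.51) and falling in pyloric caecum (-3.89 ± 0.76). Tube feet shared 9 higher genes with dermis and 4 with pyloric caecum, against 0.274 and 0.292 for independent lists, an expectation that leaves out that the tissues came from the same animals. The genes g12779, g14718, g21523 and g5179 were called higher in all 3 tissues and, like g9519, were singled out after their values were seen. In dermis g14718 reached 14891 CPM in symptomatic animals against 54.2 ± 154, and g5179 reached 2454 against 65.9 ± 145 (SD, n = 14). In tube feet the lower symptomatic library lay within the asymptomatic range for both. It held 11.9 CPM of g14718 and 26.7 of g5179, where asymptomatic libraries reached 13.9 and 29.0. Their tube feet calls thus rest mainly on 1 library each, and g21523 passed only narrowly there (adjusted p = 0.0099). The 74 shared genes were called on the symptomatic dermis and pyloric caecum libraries themselves, so high scores there follow from the choice of genes. Their mean log2 score above the asymptomatic mean was 3.70 and 4.06 in symptomatic dermis and 3.52 and 3.12 in symptomatic pyloric caecum, where asymptomatic libraries reached 0.382 and 0.737. In symptomatic tube feet, whose libraries had no part in that choice, it was 0.545 in M0D055233U and 1.16 in M0D055236X, against at most 0.418 in asymptomatic tube feet of Point Reyes. These libraries came from the same animals and batches as those used for the choice of genes. Their scores thus cannot tell disease from other traits of these animals. The Friday Harbor libraries, also without part in it, went against their labels, with 1.35 in the one labelled asymptomatic and 0.285 in the one labelled symptomatic, so the score did not separate the labels in all tube feet.

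**Figure D3:**
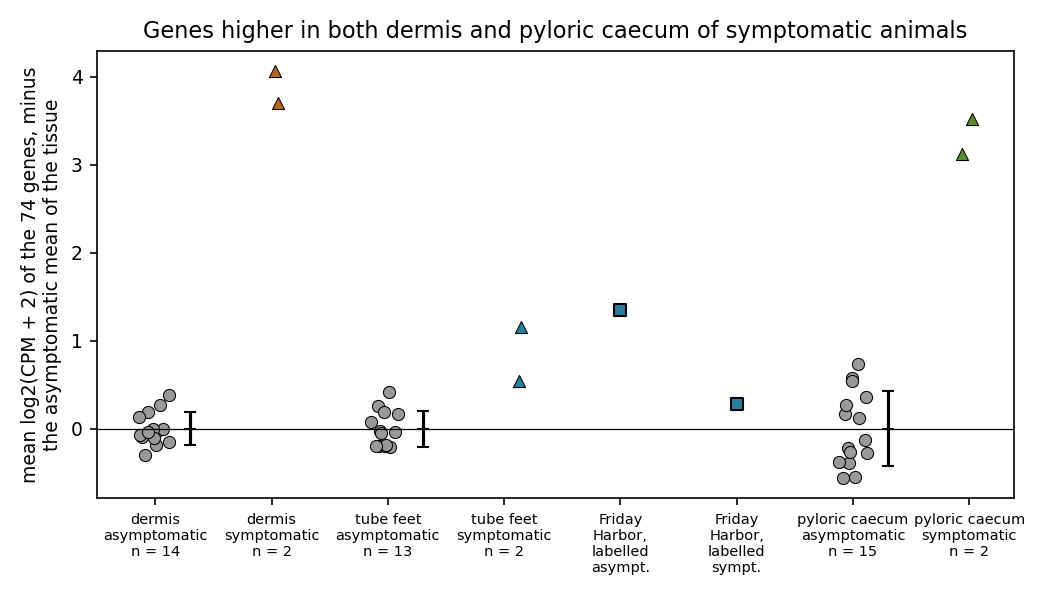
Mean log2 difference from the asymptomatic Point Reyes libraries of the same tissue over the 74 genes called higher in both symptomatic dermis and pyloric caecum, 1 point per library, with the genes chosen on the dermis and pyloric caecum libraries. Symptomatic dermis lies at 3.70 and 4.06 and symptomatic pyloric caecum at 3.52 and 3.12, while the Friday Harbor tube feet lie at 1.35 (labelled asymptomatic) and 0.285 (labelled symptomatic).

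The difference of the disease effect between tissues was tested directly. The effect differed between tube feet and dermis at 16 genes, 4 higher and 12 lower in tube feet. The 12 had positive effects in dermis, where all 12 were called, while 6 of them had positive effects in tube feet and none was among the 17 called there. Between pyloric caecum and dermis the effect differed at 27 genes, 17 higher and 10 lower in pyloric caecum. Of the 17, all had positive effects in pyloric caecum and 2 in dermis. Of the 10, all had positive effects in dermis and 1 in pyloric caecum. With animal as replicate block the counts were 48, 9 higher and 39 lower, and 41, 20 higher and 21 lower, so the lean to pyloric caecum was not kept. Without M0D055233U edgeR gave 0 and 2, with 566 and 707 at an unadjusted p under 0.05, and without M0D055236X it gave 1 and 5.

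The tissue-enriched lists asked whether symptomatic biopsies held more or less of a tissue's own genes. Each list was chosen for high values in asymptomatic libraries, which are also the reference of the disease contrast. That choice by itself favours lower values of a tissue's own list in symptomatic libraries. The tests below therefore cannot tell a loss of these genes from the way they were chosen. Most genes of the dermis and pyloric caecum lists had negative log2 fold changes in their own tissue. In dermis, 4 of the 100 dermis genes fell and none rose, over all genes tested and also adjusted over the list alone, and 89 had negative log2 fold changes. Their median was -1.51, or -1.37 with 6 genes at 0 set to their bound, against -0.18 over all genes (camera adjusted p = 1.7e-06). The adjusted p was 0.442 with an estimated correlation. In pyloric caecum, 4 of the 100 pyloric caecum genes fell, 15 adjusted over the list alone, and 89 were negative, with a median of -0.83 against -0.15 over all genes (camera adjusted p = 3.9e-08). Here the adjusted p was 0.187 with an estimated correlation. The fry test, which sets a list against no change and not against other genes, gave an adjusted p of 0.0068 for this list and 0.213 for the dermis list. The former missed 0.05 without M0D055233U (0.182) and with lists of up to 50 genes (0.0702). Tube feet genes in tube feet had a median of -0.23, with no gene past the threshold (camera adjusted p = 0.325). Own-list genes held 0.656% ± 0.238 of reads in symptomatic dermis (SD, n = 2) against 1.99% ± 1.504 (n = 14), 14.6% ± 2.498 against 21.3% ± 5.10 in pyloric caecum, and 7.85% ± 0.801 against 8.51% ± 2.48 in tube feet, where the asymptomatic library of M0D055228P held 1.38% and the other 12 held 6.69% to 11.09%. The ranges overlapped in dermis, with 0.488% and 0.825% in symptomatic libraries against 0.610% to 5.98%, and in pyloric caecum, with 12.8% and 16.3% against 15.3% to 36.04%. By size class, asymptomatic dermis held 1.94% in small, 3.86% in medium, 1.45% in large and 1.06% in x-large animals. The lists of the other tissues did not pass in any tissue. In dermis 1 tube feet gene rose, with a list median of -0.52 (adjusted p = 0.430), and the pyloric caecum list had a median of -0.15 while camera's direction was upward (0.945). In tube feet the dermis list had a median of -1.73 over 41 genes, or -0.35 with genes at 0 set to their bound (0.300), and the pyloric caecum list -0.36 (0.0600). In pyloric caecum the dermis list had a median of -0.98 over 12 genes (0.430) and the tube feet list -0.13 (0.744).

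The size comparison asked which genes change with body size in asymptomatic animals. The gene g10347 was lower in small than in x-large animals in both dermis and tube feet. In dermis its mean was 5.53 ± 4.97, 91.3 ± 68.4, 506 ± 201 and 967 ± 383 CPM from small to x-large (SD, n = 3, 3, 5 and 3), and in tube feet 63.1 ± 21.4, 841 ± 413, 1864 ± 629 and 2225 ± 473 CPM (n = 2, 3, 5 and 3). Small against x-large gave log2 fold changes of -7.31 ± 0.73 in dermis (SE; adjusted p = 4.1e-07) and -5.14 ± 0.53 in tube feet (adjusted p = 5.7e-05). These calls were kept in each alternative run. In pyloric caecum its means were 2.41, 1.77, 6.03 and 47.3 ± 85.4 CPM, with 175 CPM in 1 x-large library.

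**Figure D4:**
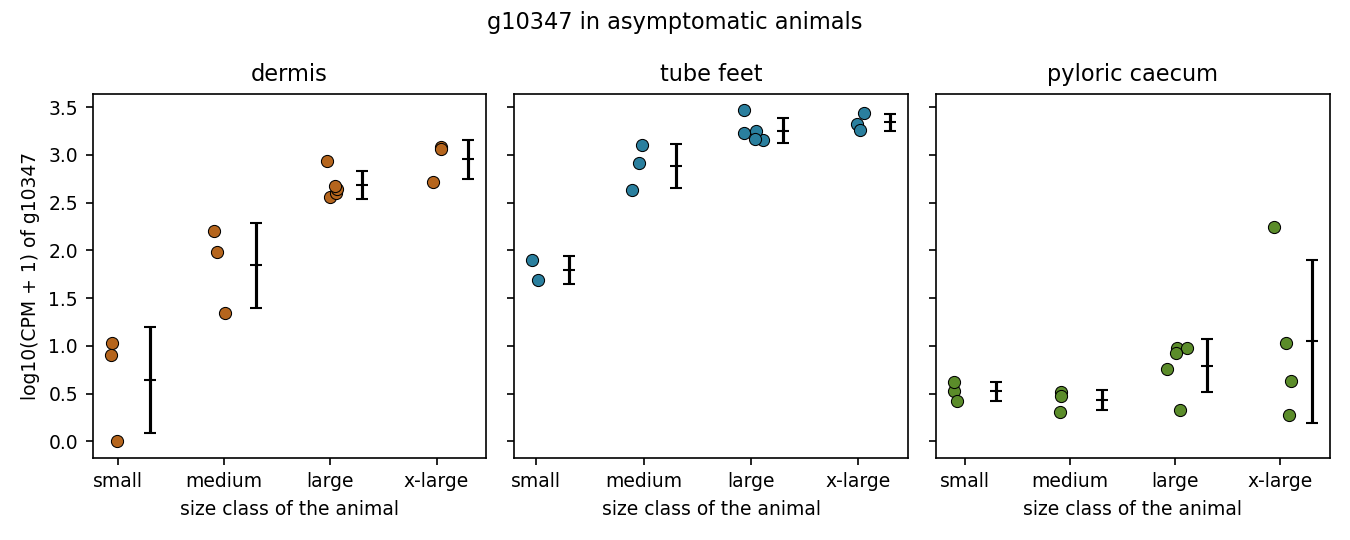
Expression of g10347 (log of CPM) in each asymptomatic library by size class and tissue, with the mean and SD of the log values per class. The arithmetic means in CPM, which are not the marks drawn, run from 5.53 in small to 967 in x-large dermis. In tube feet they run from 63.1 to 2225.

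In dermis 14231 genes were tested, and small against x-large gave 19 genes, 9 higher and 10 lower in small animals, against 22 and 15 without the feeding and Lifeboat House animals. The gene g679 stood at 43.7 ± 14.8 CPM in small animals (SD, n = 3) with no read in x-large ones (n = 3), at least 23.8-fold higher (adjusted p = 0.0012), and g3729 at 139 ± 209 CPM against 1 read, a ratio of 247 (95% interval 44.1 to 9805; adjusted p = 0.0023). Lower in small animals after g10347 was g6826, at 3.58 ± 5.06 against 251 ± 153 CPM (log2 fold change -6.21 ± 0.70, adjusted p = 3.6e-06). Against the mean of the other classes, small had 23 genes higher and 7 lower, medium 47 and 2, large 3 and 0, and x-large 9 and 0. The directions of x-large rest on the setting, with 12 higher and 16 lower with batch, 20 and 29 without the feeding and Lifeboat House animals, 8 and 9 by DESeq2 and 47 and 45 with no filter, and small had 18 and 21 by DESeq2. The 3 of large dermis, named after their values were seen, were g10347 (2.64 ± 0.37), g14490 (2.02 ± 0.32) and g6036 (1.95 ± 0.30). The medium count of 49 was 8 without M0D055223K, 13 without M0D055222J, 32 without M0D055219G, 79 without M0D055226N, 94 without M0D055225M, and 0 by edgeR with the number of genes with a read as a covariate (891 at an unadjusted p under 0.05). Medium dermis libraries held 10640 ± 289 genes with a read (SD, n = 3), against 13607 ± 551 in small, 12261 ± 1484 in large and 12951 ± 866 in x-large dermis. Dermis-list genes held 3.86% ± 2.39 of the reads of medium dermis. For large it was 1 without M0D055219G, M0D055221I, M0D055222J or M0D055227O and 5 without M0D055220H. For x-large it was 5 without M0D055228P, 16 without M0D055225M and 20 without M0D055232T, and for small against x-large 29 without M0D055225M. The call of g679 was lost without M0D055221I (adjusted p = 0.0156) or M0D055228P (0.0171). The call of g3729 was lost without M0D055219G (0.356), M0D055228P (0.0224), M0D055229Q (0.0141) or M0D055231S (0.0171), and by DESeq2 (0.0193). Its log2 fold change was 7.36 with all libraries and 4.50 without M0D055219G. That library held 380 CPM, and the other small ones held 3.75 and 33.3, so the size of the difference rests mainly on 1 library.

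In tube feet 15200 genes were tested, and small animals stood apart from the mean of the other classes with 107 genes higher and 11 lower. Small against x-large gave 18 higher and 4 lower. The gene g20110 stood at 39.4 ± 20.1 CPM in small animals (SD, n = 2) against 1 read in x-large ones (n = 3), a ratio of 82.1 (95% interval 14.1 to 3300; adjusted p = 0.0069), g18733 at 221 ± 195 against 4.65 ± 1.54 CPM (log2 fold change 5.48 ± 0.96, adjusted p = 0.0098), and g1830 at 14.0 ± 0.104 against 167 ± 66.2 CPM (-3.55 ± 0.55, adjusted p = 0.0047). The gene g18733 belongs to the dermis list, with 2958 to 3617 CPM in small dermis. Dermis-list genes held 0.0694% of the reads in small tube feet (0.0945% in M0D055219G) against 0.0217% in x-large tube feet, and 0.0999% in the medium library of M0D055224L, where g18733 stood at 194 CPM. Large animals had 2 genes higher, g10347 (1.92 ± 0.26) and g16655 (5.90 ± 0.83), and x-large animals 1, g10347 (2.27 ± 0.28), named after their values were seen. By DESeq2, large had 14 higher and 10 lower and x-large 8 and 6, and with no filter large had 9 and 40. Medium had 0 by edgeR, with 547 at an unadjusted p under 0.05 and 0 by DESeq2. The small count of 118 was 3 with batch as a covariate. Without M0D055220H it was 10 and without M0D055219G 46, but these fits hold a lone small library, whose spread the other classes supply, so they do not test the class, and the same holds below for small against x-large. That of small against x-large was 5 without M0D055219G, 7 without M0D055220H, 10 without M0D055225M, 4 without M0D055228P, 3 without M0D055230R, 38 without M0D055231S, 5 with batch and 106 by DESeq2. For medium it was 2 without M0D055222J or M0D055223K. For large it was 1 without M0D055224L or M0D055225M, 4 without M0D055228P, 5 without M0D055230R and 0 by edgeR without M0D055219G, M0D055220H, M0D055222J, M0D055226N, M0D055227O or M0D055231S (1243 to 1469 at an unadjusted p under 0.05). For x-large it was 0 by edgeR without M0D055220H or M0D055228P (992 and 803 at an unadjusted p under 0.05), 2 without M0D055230R and 3 without M0D055231S. The call of g20110 was lost with batch (adjusted p = 0.302) and without M0D055220H (0.154), M0D055230R (0.0354), M0D055219G (0.0188), M0D055231S (0.0188), M0D055228P (0.0169), M0D055225M (0.0116) or M0D055227O (0.0101). The call of g18733 was lost without M0D055219G (0.131), M0D055230R (0.0571), M0D055231S (0.0241), M0D055228P (0.0235), M0D055225M (0.0150), M0D055226N (0.0135), M0D055232T (0.0127), M0D055234V (0.0114) or M0D055227O (0.0111), and that of g1830 without M0D055220H (0.0767), M0D055219G (0.0440), M0D055230R (0.0148) or M0D055228P (0.0126). Without the feeding and Lifeboat House animals g20110 (0.0167) and g18733 (0.0334) also missed the threshold.

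In pyloric caecum 13220 genes were tested, and small against x-large gave 39 genes, 19 higher and 20 lower in small animals. That balance rests on the setting, with 14 and 32 without the feeding and Lifeboat House animals and 79 and 106 by DESeq2. The gene g811 stood at 36.4 ± 19.4 CPM in small animals (SD, n = 3) with no read in x-large ones (n = 4), at least 41.9-fold higher (adjusted p = 0.0053), and g11410 at 115 ± 83.4 against 2.03 ± 2.37 CPM (log2 fold change 5.75 ± 1.10, adjusted p = 0.0099). The gene g13935 had no read in small animals against 80.3 ± 31.0 CPM, at least 54.9-fold lower (adjusted p = 0.0023), and g18208 had 3 reads against 445 ± 234 CPM, an x-large to small ratio of 284 (95% interval 96.9 to 1377; adjusted p = 0.0017). Small had 30 genes higher and 4 lower than the mean of the others, and x-large 17 and 0, against 72 and 54, and 54 and 16, by DESeq2. Medium had 0 by edgeR, with 514 at an unadjusted p under 0.05 and 1 by DESeq2, and large had 0 by edgeR, with 896 and 16. The count for small against x-large was 0 by edgeR without M0D055219G (1193 at an unadjusted p under 0.05), 3 without M0D055220H, 5 without M0D055221I, 19 without M0D055228P, 10 without M0D055229Q, 9 without M0D055230R, 23 without M0D055231S, 68 without M0D055232T, 19 with batch and 185 by DESeq2. For small it was 11 without M0D055219G, 21 without M0D055220H, 18 without M0D055221I, 20 without M0D055224L and 61 without M0D055232T. For x-large it was 11 without M0D055219G or M0D055221I, 8 without M0D055229Q, 26 without M0D055228P or M0D055231S, 29 without M0D055232T, and 0 by edgeR with batch (839 at an unadjusted p under 0.05). For medium it was 1 without M0D055223K, and for large 1 without M0D055222J or M0D055232T. Leaving out M0D055219G, M0D055220H or M0D055221I ended the calls of g811 (adjusted p up to 0.0216), g11410 (0.0547), g13935 (0.0302) and g18208 (0.0163), and g811 and g11410 also lost theirs with batch (0.0508 and 0.0417). The call of g811 was lost as well without M0D055229Q, M0D055230R or M0D055231S (0.0102 to 0.0117), and that of g11410 without any of these (0.0235 to 0.0343), without M0D055228P (0.0294), M0D055225M (0.0131) or M0D055227O (0.0113), and without the feeding and Lifeboat House animals (0.0146).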

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

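All tests of explanations and all counts of splits given here were chosen only after the results were seen, while the interaction tests and the groups compared were planned. Of 34 groups of 4 to 10 libraries tested for a library far from the others, 12 had one. In 3 of the 12 the other libraries held no read of the gene, so that any read at all stood apart, and in 9 they held values. The rate of about 1 in 20 that chance gives in this test holds for normally spread values. CPM of single genes need not be spread so, and most of the genes tested had been picked for size differences. The 12 can thus not be set against that rate, and they are listed as description only.

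Between the Friday Harbor tube feet libraries of animal M0D055239A, the genes called with disease at Point Reyes moved against the labels. Of 17 tube feet calls, 2 had the sign expected from the labels (11.8%, exact 95% interval 1.46 to 36.4), of 303 dermis calls 74 (24.4%, 19.7 to 29.7), and of 326 pyloric caecum calls 103 (31.6%, 26.6 to 36.9), while 47.3% of all 15249 genes were higher in the library labelled symptomatic; genes of 1 pair of libraries are not independent, so the intervals hold no error between libraries or animals. The tables argue against the depth of the 2 libraries, which held 668459 and 663143 gene reads: the genes called higher in dermis had a median difference of -0.63, lower than every one of 10000 random lists of like expression. Exchanged labels are a candidate explanation, since the library labelled asymptomatic scored 1.35 on the 74 shared genes, above the highest asymptomatic Point Reyes tube feet library at 0.418, and the one labelled symptomatic scored 0.285, within their range. A response already under way in tissue that looked healthy may give the same values. It was not tested, and the labels were kept as given. The libraries also differed in tube feet list genes, with 4.09% of reads in the one labelled asymptomatic and 7.62% in the other. Among asymptomatic Point Reyes tube feet, M0D055228P had the lowest share (1.38%) and the highest score (0.418). Symptomatic Point Reyes tube feet held 7.29% and 8.42%, with scores of 0.545 and 1.16. Whether this share bears on the score was not tested.

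The 74 genes called higher in both symptomatic dermis and symptomatic pyloric caecum were more than other groupings gave: 1 of 100 splits, the real one, gave as many, and the highest other split gave 2. The other splits called a median of 1 gene in dermis and 0 in pyloric caecum, so large overlaps could hardly occur in them. These splits therefore do not test sharing apart from the count of each tissue. The tables argue against RNA carried over between the biopsies, because the shared genes would need a median of at least 40.7% dermis RNA in pyloric caecum, where the dermis genes allow at most 0.371%, and at least 96.0% pyloric caecum RNA in dermis, where the limit is 1.04%. They also argue against a difference between batches as the whole cause, since the lowest median difference of these genes from asymptomatic libraries of the same batch and tissue was 2.59 on the log2 scale. In batches 2 and 5 these were 4 and 2 libraries in dermis, but only 1 and 2 in pyloric caecum. The 74 genes had been called against them among others. With batch as a covariate the median of their log2 fold changes (± median SE) went from 3.59 ± 0.458 to 3.42 ± 0.584 in dermis and from 3.30 ± 0.53 to 3.18 ± 0.835 in pyloric caecum. With these larger errors 56 kept the call in dermis, 15 in pyloric caecum and 13 in both. A response to wasting disease shared by body wall and digestive gland may underlie them, as a hypothesis that rests on 2 animals, which also differ from the others in whatever else was not labelled.

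In medium dermis, 49 genes differed from the mean of the other size classes, where 1 of 100 splits gave as many, the real one. The highest other split gave 25, with the 3 small animals as its group, which is a size class and no mixture of classes, and the next gave 18. The tables argue against depth, since 63 genes were called after thinning every library to 373930 reads, 46 of the 47 higher genes among them. The number of genes detected per library cannot be told apart from size class: the medium class had the lowest mean number of genes with a read, also after thinning (10522 ± 379, against 11802 ± 1444 to 12895 ± 360), although the large library of M0D055226N then held fewer (9647) than any medium library, and with that number as a covariate the median of the 47 higher genes went from 2.82 ± 0.460 to 1.68 ± 0.720 and no call was left, as the effect fell and its error grew. A difference of medium-sized animals could also give such values, and it was not tested apart from library complexity.

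The disease effect differed between tissues by a test of the difference itself at 16 genes for tube feet against dermis and at 27 for pyloric caecum against dermis. Animal M0D055226N held the highest large dermis library for g10347, at 857 CPM with the next at 476, and 48.03% of that library's gene reads fell in 10 genes, where the next library had 17.9%. The large dermis library of M0D055227O was the only one of its class with g679, at 4.93 CPM, and that of M0D055225M had g3729 at 13.9 CPM with the next at 2.59. In large tube feet, g10347 stood at 2955 CPM in M0D055225M with the next at 1768, and g20110 at 1.69 CPM in M0D055227O with no read in the others. In large pyloric caecum, M0D055226N had g811 at 2.85 CPM, with no read in the others, and g11410 at 50.3 CPM, with the next at 11.3. Also in large pyloric caecum, M0D055225M had the fewest genes with a read, 11679 with the next at 13119, and M0D055227O the lowest share of reads in 10 genes, 24.5% with the next at 37.6%. In x-large pyloric caecum, g10347 stood at 175 CPM in M0D055229Q with the next at 9.61, and genes of the pyloric caecum list held 24.8% of the reads in M0D055228P with the next at 16.4%.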

How the results depend on the processing

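The fits without a library that stood apart and those with the number of genes with a read were chosen only after the results were seen, and the other alternatives were planned. The tissue counts were stable: outside filterByExpr (3815, 3489 and 2969 for pyloric caecum against dermis, pyloric caecum against tube feet and dermis against tube feet), which tests fewer genes, and a minimum fold of 2 (3089, 3370 and 1284), which asks for more, each stayed within 1.5 times. DESeq2 size factors shifted the median of all genes by 0.11 for pyloric caecum against dermis, and the share of higher genes among the calls went from 49.7% to 55.4%, and with filterByExpr that of dermis against tube feet went from 42.3% to 54.1%, so splits of direction rest on scaling and filter. Named genes kept their call 255 times and lost it 29 times over the alternatives (in 4 more cases DESeq2 gave no adjusted p), kept it 278 times and lost it 67 times over the fits without 1 library, and none changed direction. Where a value below moved, the cause was not tested, except that leaving out libraries leaves fewer samples. Disease calls rest on 2 animals and size classes on 2 to 5 libraries. In the simulations of the disease and small against x-large comparisons, 4.48% to 19.4% of the 4-fold changes were called. Of the 8-fold changes 33.3% to 53.0% were called. Most differences of 4-fold and many of 8-fold can thus go uncalled.

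Disease counts are in the order dermis, tube feet and pyloric caecum. With batch as covariate they were 196, 1 and 27, and with McClures Beach libraries only 147, 1 and 183. The DESeq2 Wald test gave 51 in tube feet and 550 in pyloric caecum. In tube feet, size class as covariate gave 8, the robust fit 7, and the Friday Harbor pair 0 by edgeR (999 at an unadjusted p under 0.05). Without 1 library the counts ranged from 150 to 340, 3 to 21 and 69 to 437. With animal as replicate block, the disease effect differed at 48 genes for tube feet against dermis and 41 for pyloric caecum against dermis, and without 1 symptomatic animal at 0 to 1 and 2 to 5.

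Size counts in dermis are in the order small, medium, large, x-large and small against x-large. They were 131, 182, 49, 92 and 85 with no filter and 52, 78, 8, 49 and 37 without the feeding and Lifeboat House animals. Batch as covariate gave 16 for large and 28 for x-large. The DESeq2 Wald test gave 89 for medium, 17 for x-large and 29 for small against x-large. The number of genes with a read as covariate gave 0 for medium (891 at an unadjusted p under 0.05) and 5 for x-large. Without 1 library, medium ranged from 8 to 94, large from 1 to 5, x-large from 5 to 20 and small against x-large from 13 to 29.

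In tube feet, in the same order, no filter gave 228, 11, 49, 12 and 133. Batch as covariate gave 3 for small, 1 for large, 2 for x-large and 5 for small against x-large. The DESeq2 Wald test gave 24, 14 and 106 for the last 3. Without the feeding and Lifeboat House animals they were 0 (1434 at an unadjusted p under 0.05), 3 and 34. Without 1 library, small ranged from 10 (with 1 small library left) to 171, medium from 0 to 2, large from 0 to 5, x-large from 0 to 3 and small against x-large from 3 to 38.

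In pyloric caecum, no filter gave 135, 2, 32, 100 and 150, and the DESeq2 Wald test 126, 1, 16, 70 and 185. Batch as covariate gave 0 for x-large (839 at an unadjusted p under 0.05) and 19 for small against x-large. Without the feeding and Lifeboat House animals, x-large had 34. Without 1 library, small ranged from 11 to 61, medium and large each from 0 to 1, x-large from 8 to 29 and small against x-large from 0 to 68.

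With an estimated inter-gene correlation the own lists kept their medians of -1.51 in dermis and -0.83 in pyloric caecum but lost the call (adjusted p = 0.442 and 0.187). Changes of sign came in lists that had not passed: the pyloric caecum list in dermis, with a median of 0.061 for lists of up to 50 genes, and the tube feet list in pyloric caecum, with medians from -0.78 to 0.27 without 1 symptomatic animal.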

Other observations

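All tests given here, the counts of splits among them, were chosen only after the results were seen. Feeding state and body colour were compared within asymptomatic McClures Beach animals. No test separated feeding from batch, animal or size, or colour from size. The feeding animals were x-large and large, while all small and medium animals were among those not feeding. Among asymptomatic McClures Beach animals, 18 genes were higher in the pyloric caecum of the 2 feeding animals than in 12 others and none was lower. For 11 of the 18, each feeding library lay above all the others. One of them was the size gene g6826, singled out after its values were seen, at 112 and 280 CPM against at most 25.9 in the others (log2 fold change 4.60 ± 0.67, adjusted p = 0.0015). The gene with the lowest p, g3547, stood at 387 CPM in 1 feeding library and at 3.53 in the other, where the others reached 5.58, so its call rests on 1 animal. Of the 91 splits of these libraries, 1 gave as many genes as the 18, and the highest other gave 7. Feeding animals had 1 higher gene in dermis, and in tube feet 0 by edgeR, with 506 at an unadjusted p under 0.05; DESeq2 was not run here. Orange and brown animals differed at 9 genes in tube feet, 2 in pyloric caecum and 0 in dermis by edgeR, with 1391 at an unadjusted p under 0.05 in dermis, and every small animal was orange.

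The size trend across the 4 classes, in steps of 1 class, called 25 genes in dermis (7 rising and 18 falling), 73 in tube feet (5 and 68) and 83 in pyloric caecum (41 and 42). The dermis and tube feet trends shared 6 genes in the same direction, against 0.101 for independent lists. That expectation leaves out that most of these libraries came from the same animals. The slope of g10347 was 2.38 ± 0.29 log2 units per class in dermis (adjusted p = 1.1e-05), 1.39 ± 0.27 in tube feet (0.0091) and 1.85 ± 0.40 in pyloric caecum (0.0125, not past the threshold), which ranked it 4 in dermis and 70 in tube feet by p. In pyloric caecum the x-large library of M0D055229Q held 175 CPM and the next library 9.61. The x-large library of M0D055231S held 0.891 CPM. The slope there may thus rest mainly on 1 library, and the trend was not fitted without it. For the 3 counts and the 6 shared genes, 1 of 100 splits of the size labels, the real one, gave as many, and the highest other splits gave 5, 9, 3 and 0. The other splits called a median of 0 genes in each tissue, so they do not test the sharing of 6 genes apart from the counts.

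A term for the animal passed the threshold across tissues at 638 of 15207 genes (4.20%) in 42 libraries of 15 animals. Among the disease calls the share was 8 of 17 in tube feet (47.1%), 29 of 304 in dermis (9.54%) and 13 of 354 in pyloric caecum (3.67%). Called genes also lay next to each other in ID number more often than random genes did. In dermis 38 pairs of disease calls had consecutive IDs, where 10000 random draws averaged 5.60 and reached 15, and in pyloric caecum 29, where they averaged 7.27 and reached 19 (1-sided permutation p = 1e-04 each, the smallest these draws can give). Whether consecutive IDs are neighbours on a chromosome is not given in the sources used here.

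For the disease counts, only the real split of 100 gave as many in dermis (324, highest other 10) and in pyloric caecum (363, highest other 47). These fits held no batch term, and with batch as a covariate the pyloric caecum count fell below that 47. The splits show that this pair of animals stood apart. They cannot tell disease from site, size, batch or other traits of the pair. As many as the 6 shared lower genes came from 1 of 100 splits (highest other 0). For the higher genes that tube feet shared with dermis (9) and with pyloric caecum (4) it was 1 of 91 and 1 of 100 splits (highest other 1 each). Each split moved both tissues of an animal together. Within single tissues, the other splits called a median of 1 gene in dermis, 1 in tube feet and 0 in pyloric caecum. With so few calls such overlaps could hardly occur, so these splits do not test sharing apart from the count of each tissue. With batch as a covariate tube feet had 1 call, so the overlaps of 9 and 4 are not kept in that fit. For the 17 of tube feet, 3 of 100 splits gave as many and the highest other also gave 17, with M0D055219G and M0D055236X as the pair, so the call rests partly on M0D055236X. The tissue counts of 6013, 5781 and 4520 were each reached by 1 of 100 splits, with highest others of 129, 178 and 486. With tissue labels shuffled within animals, each was again reached by 1 of 100 splits, with highest others of 2371, 42 and 2913.

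For size in dermis, 1 of 100 splits gave as many as the 30 of small (highest other 29) and the 19 of small against x-large (highest other 15). In the split that gave 29 and in the one that gave 15, the small class was the real one, with the labels of the other classes moved, and the next highest gave 13 and 1. In dermis too, 3 splits gave as many as the 3 of large (highest other 4) and 4 splits as many as the 9 of x-large (highest other 15). For tube feet, 1 of 100 splits gave as many as the 118 of small (highest other 10) and the 22 of small against x-large (highest other 1). As many as the 2 of large came from 3 splits: the real one, 1 that gave 65 and 1 that gave 17, both several times the real count. In the split with 65, the group of 5 held both small libraries, with M0D055222J, M0D055223K and M0D055228P, so that split is not free of size. The 1 of x-large was reached in 9 splits (highest other 2, in a split whose group held both small libraries), so chance cannot be excluded for it. For pyloric caecum, 1 of 100 splits gave as many as the 34 of small (highest other 6), the 17 of x-large (highest other 5) and the 39 of small against x-large (highest other 1). For medium tube feet and medium and large pyloric caecum, with 0 by edgeR (547, 514 and 896 at an unadjusted p under 0.05), all 100 splits gave as many by construction, so the splits decide nothing; their highest others were 2, 5 and 8, and the split with 8 held the 3 small animals in its group.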
